A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 12 samples.

How the data were processed

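RNA polymerase occupancy was profiled in Synechococcus elongatus PCC7942, wild type and rel-, by chromatin immunoprecipitation and sequencing. Per the labels' protocols, cells entrained to light and dark were fixed with formaldehyde at each time point, and sheared chromatin was precipitated with a monoclonal antibody against the RNA polymerase β subunit. Mouse IgG served as the mock, with time points combined. The series' design text describes an mRNA preparation, while the labels and protocols of all 12 libraries describe chromatin immunoprecipitation, and the latter was followed here. The deposited table gives 1 stalling index, a ratio within 1 library, per region and library. Per the submitters' processing notes, Bowtie 0.12.7 was used. The genome build, the formula of the index, read filters and the choice of regions are not given in the sources used here. The table gives no read counts, so depth is unknown and no counting interval can be set on an index.

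The table has a start, an end, a strand and 12 columns of indices, matched to samples by their titles, with 0 columns of other samples. It runs through the chromosome once with 349 intervals, of which 348 match exactly 1 annotated gene, and again with 412 intervals, of which 406 hold 2 or more annotated genes. No value was missing or at 0, and no region was shorter than 600 bp. Of the intervals in the first part 36 overlap 1 in the second part on the same strand. Gene names were taken from a RefSeq annotation of another assembly of this strain, which names genes without strand or product. A gene was assigned when at least a share of 0.8 of it lay in the region, and boundaries within 4 bp were taken as equal: 655 regions matched at both ends and 759 at one end at least. Of the 761 regions 318 hold a gene with a symbol, and others carry locus tags. Regions with several genes are named by their first and last gene on the region's strand.

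Indices were analysed as log2 of the deposited ratio with no pseudocount. In darkness, a region counted as higher or lower when it differed by at least 1.5-fold in one direction at each of the 3 dark times, and in comparisons of single libraries when it differed by at least 1.5-fold. With 1 library per strain and time point these counts have no replicate check and no p-value. Counts of each comparison stand beside the mean of 100 simulations without any change, except those comparing darkness changes between the strains. Noise was drawn from the difference between the 8 h and 12 h libraries of a strain. This noise covers only the spread between those libraries, the most alike of each strain, and is a minimum. Where a mean change in darkness carries an SD, it is over the 3 dark times, which are not replicates. Most mean changes are given without one. The strain difference over all 5 times was tested with limma 3.58.1 in R 4.3.3 on log2 indices, with time point as a block and Benjamini-Hochberg adjustment at a threshold of 0.05. The median log2 index was tested with an exact two-sided sign-flip permutation over the 5 time points. Nothing in the labels says whether the time points came from separate cultures, so the p-values measure only the spread between these libraries. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

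The steps were tested on simulated data with a noise SD of 0.4 (log2) and 761 regions, of which 50 were changed at each fold size. For the strain difference over the time course, limma recovered 36% of regions changed 1.5-fold, 92% at 2-fold and 100% at 4-fold and 8-fold, with 3 false among 167 calls. For wild type in darkness against dusk, the fold rule recovered 12% at 1.5-fold, 44% at 2-fold and 100% at 4-fold and 8-fold, with 41 false among 169 calls. The simulated noise was independent between libraries, and the simulated strain difference was the same at every time. The real dark libraries are alike and the real strain difference varies over time, so these rates check the steps only.

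The comparisons, tests, naming rule, 19 gene lists and most alternatives were set before the data were examined. Named were the 10 highest and 10 lowest regions in each dark comparison, ranked by the smallest absolute log2 change of the 3 dark times, and the 5 highest and 5 lowest for dawn against 12 h in each strain and for the strains at dusk. Also named were the 5 regions with the smallest limma p in each direction, the 2 highest and 2 lowest members of each list, and sigma factor genes. The text leaves out some of these, and a few other list members are named beside list counts, chosen after their values were seen. Lists were matched by gene symbol only, and the median of a list with 3 or more regions was placed among 10000 random lists matched on deciles of mean index. A region with several genes can be in several lists, so counts of different lists are not independent. Alternatives were centring on library medians, division by the mock index, a pseudocount of 0.1, removal of the lowest 20% by mean index, a 2-fold threshold, leaving out each time point, and limma without the time block or with trend and robust moderation. Chosen after the data were seen were filters on upstream genes, interval type, overlap and mock index, division by mocks with exchanged labels, limma on the dark times alone, the translation list with exact symbols and counts per list on the centred scale.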

Results

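The data were RNA polymerase stalling indices from chromatin immunoprecipitation and sequencing in the cyanobacterium Synechococcus elongatus PCC7942. Cells of the wild type and of a strain labelled rel- were grown in cycles of 12 h light and 12 h dark. Rel enzymes make and break down (p)ppGpp, the alarmone of the bacterial stringent response, and the comparisons ask how polymerase stalling responds to darkness with and without a working rel gene. Each strain was sampled at dusk, after 4, 8 and 12 h of darkness and at dawn with an antibody against the β subunit of RNA polymerase. There was 1 library per strain and time point, giving 10 polymerase libraries, and 1 mouse IgG mock library per strain with its time points combined. No value below therefore has a replicate error. Read counts are not given in the table, so the depth behind each index is unknown. The table held 761 regions of 1002 to 8662 bp, in a first part of 349 intervals, of which 348 matched 1 gene, and a second part of 412 that mostly held several genes. A stalling index generally sets polymerase signal near the start of a gene against signal further along it. The formula behind these values is not given in the sources used here. The dawn samples are titled dawn but carry a label that also names darkness, so whether the light was already on is not given either. Coordinates are those of the table, whose genome build is not stated, and gene names come from another assembly of the same strain. The rel gene itself, the kai genes, rpaA and rpaB were not matched by name and are not analysed here.

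Wild type had a higher median index than rel- at dusk and throughout darkness, and a lower one at dawn. The wild-type median was 1.93 at dusk, 2.03 at 4 h, 2.00 at 8 h, 2.01 at 12 h of darkness and 1.63 at dawn. The rel- medians were 1.56, 1.58, 1.49 and 1.47 over the same first 4 times and 1.89 at dawn. Regions with an index above 2 made up 49.1% of wild-type regions at dusk and 40.3% at dawn, against 34.4% and 46.0% in rel-. Both mock libraries were far lower and alike, with medians of 1.16 and 1.15 and with 8.15% and 6.18% of regions above 2. Within a strain the dark libraries resembled each other most, with Pearson's r across regions of 0.91 to 0.98 in wild type and 0.90 to 0.97 in rel-. The index spread was wider at 12 h of darkness than at dusk in wild type (SD of log2 index 1.29 and 1.06) and in rel- (1.14 and 0.97). Across regions, the library labelled wild-type mock had r of 0.43 to 0.55 with the wild-type polymerase libraries and 0.54 to 0.62 with the rel- ones. The library labelled rel- mock had r of 0.36 to 0.43 with the rel- polymerase libraries and 0.33 to 0.45 with the wild-type ones. The 2 regions of psbA, which encodes the D1 protein of photosystem II, had high mock indices of 7.19 to 18.1, while the annotation used holds 3 psbA genes. Near-identical copies can share reads, so their values are uncertain.

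**Figure D1:**
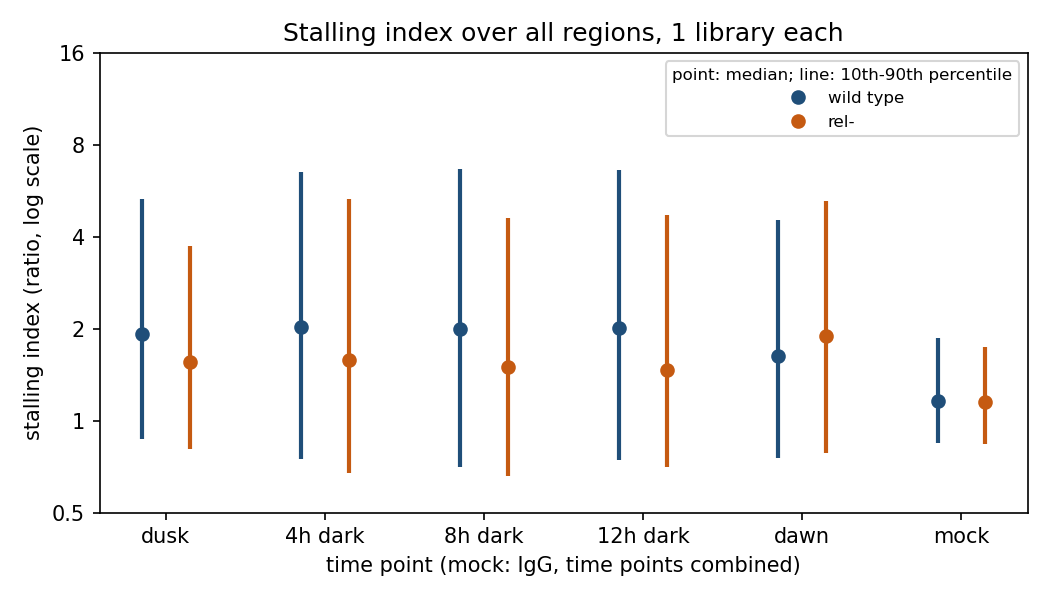
Stalling index (log axis) by time point in wild type and rel-, with the median over 761 regions as a point and the 10th to 90th percentile as a line, 1 library each. The wild-type medians lie between 1.93 and 2.03 up to 12 h of darkness and at 1.63 at dawn, the rel- medians between 1.47 and 1.58 and at 1.89 at dawn, and both mocks near 1.16.

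In wild type the regions with the highest ratios of dark to dusk index included those of atpH, ndhN and glyA and the ribosomal protein operon from rplC to rplO. The region ending in atpH, which encodes a subunit of the F-type ATP synthase (positions 329764 to 330831), had an index of 3.70 at dusk and 34.4, 33.5 and 39.8 at 4, 8 and 12 h of darkness. That was 9.68-fold higher on average (log2 change 3.27 ± 0.13, SD over the 3 dark times). The ribosomal protein operon from rplC to rplO was 2.83-fold higher, with 28.4, 38.6 and 30.4 in darkness against 11.3 at dusk. The region of ndhN, a subunit of the NDH-1 complex, and trmD was 3.84-fold higher, and the region beginning with glyA, which encodes serine hydroxymethyltransferase, was 2.98-fold higher. The lowest ratio was in the 3-gene region QY054_RS01660 to QY054_RS01650, 10.5-fold lower than at dusk, followed by the region of ccmN, a carboxysome assembly gene, which was 6.26-fold lower.

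By the fixed rule of at least 1.5-fold in one direction at each of the 3 dark times, 92 of the 761 regions were higher and 72 lower than at dusk. After centring on library medians the counts were 75 higher and 83 lower, so neither direction prevailed on both scales. With noise as large as the difference between the 8 h and 12 h libraries and no other change, simulation gave 2.01 higher and 1.99 lower on average. The 8 h and 12 h libraries are the most alike of each strain (r 0.98 in wild type and 0.97 in rel-), so this noise and the values from it below are a minimum. Other regions at the upper end were sufU with its neighbours (3.48-fold) and QY054_RS04040 with QY054_RS04045 (4.76-fold). The single genes QY054_RS10590 (3.14-fold), QY054_RS11840 (2.63-fold), QY054_RS02820 (2.91-fold) and QY054_RS07275 (3.19-fold) were there as well. At the lower end were the region of rpsR, encoding ribosomal protein S18 (5.19-fold lower), and that of the mismatch repair gene mutS (4.03-fold lower, 14.4 at dusk and 3.10 at 12 h). The single genes QY054_RS06880 (4.48-fold lower), QY054_RS02135 (4.18-fold lower) and QY054_RS06385 (3.65-fold lower) also had higher values at dusk. The sigma factor gene rpoD had 8.08 at dusk and 16.8, 22.7 and 21.5 in darkness, a log2 change of 1.32 ± 0.23. The other sigma factor region, sigC, stayed between 1.81 and 2.29.

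Among the gene lists, 3 of 7 ribosomal protein regions were higher, 1 was lower and 3 were neither. The higher ones were the rplC to rplO operon, the region of secE, nusG and rplK (log2 change 1.15) and that of rseP and rpsN (0.93), and the lower one was the rpsR region (-2.38). Of 8 photosystem II regions 1 was higher, the region of psbQ and thiL (1.23), and 1 psbA copy was lower (-0.88). Of 4 regions with cytochrome or other electron carrier genes 2 were lower, those of petJ and QY054_RS01215 (-1.60) and of hemE and petE, the plastocyanin gene (-1.30). In the chaperone and protease list 3 of 11 regions were lower, dnaJ (-1.11), ftsH (-0.83) and clpB (-0.71), and none was higher. The ndhN region was the 1 higher and the ndhI region (-1.06) the 1 lower of 6 NDH-1 regions. The glycogen and pentose phosphate list (5 regions) and the replication and division list (7 regions) had no region past the rule. In the translation list 5 of 25 regions were higher and 3 lower. Its symbol pattern also took in genes outside translation, such as manS, mutS and glmS, and with exact symbols alone 2 of 16 were higher, those of trpS (1.28) and tyrS (0.84), and 1 lower, that of prfB (-0.64). Carbon fixation had 1 of 3 regions lower, that of ccmN. Chlorophyll and haem synthesis had 1 of 5 lower, the region of hemE and petE already counted with the electron carriers. Of the 3 regions with RNA polymerase or Nus factor genes, that of nusG, already counted with the ribosomal proteins, was higher. None of the 2 phycobilisome and 2 clock-related regions passed the rule, and the psaA to psaB region, the photosystem I core, did not pass it either (0.31). The nitrogen assimilation, transfer RNA and ppGpp lists matched no region.

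In rel- the highest ratios of dark to dusk index were at polA and at QY054_RS12455, neither of them near that size in wild type. The index of polA, the DNA polymerase I gene (positions 192655 to 195516), was 1.36 at dusk and 34.6, 58.4 and 79.9 at 4, 8 and 12 h, 40.2-fold higher on average. In wild type it was 4.28 at dusk and 12.2, 8.77 and 6.50 in darkness. QY054_RS12455 had 1.01 at dusk and 9.57, 30.1 and 42.4 in darkness (22.8-fold), and the atpH region was 7.52-fold higher, from 2.01 to 14.8, 14.1 and 16.5. The glycyl-tRNA synthetase gene glyS was 4.51-fold higher (3.80 at dusk and 15.5 to 18.4 in darkness). The region of fbt and QY054_RS01005 was 15.7-fold lower, with 2.68 at dusk and 0.121 at 12 h, and wecB, a gene of cell-envelope sugar synthesis, was 5.40-fold lower.

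The rule counted 96 regions higher and 121 lower than at dusk in rel- (100 and 122 after centring), where noise alone gave 1.09 and 2.77 on average. The upper end also held QY054_RS05640 (8.70-fold) and QY054_RS07200 (4.09-fold). The lower end held QY054_RS12500 (log2 change -3.17), QY054_RS01380 with QY054_RS01375 (7.33-fold lower) and QY054_RS01660 to QY054_RS01650 (6.42-fold lower). The gene rpoD, with 3.20 at dusk and 3.76, 3.44 and 4.96 in darkness, did not pass the rule. In the photosystem II list 4 of 8 regions were higher, the 2 psbA regions, the region of psbQ and thiL (1.74) and that of psb28 (1.60). Both ATP synthase regions were higher, with log2 changes of 2.91 and 1.34. Of the 7 ribosomal protein regions 3 were higher, among them rplC to rplO (1.47), and 2 lower, among them rpsR (-1.85). Electron carrier regions were lower in 3 of 4 cases, and chlorophyll and haem regions in 3 of 5, with the hemL region higher (0.89). The lower regions of hemE with petE and of petP with chlG are counted in both lists. In the chaperone list ftsH (-1.89), dnaJ (-1.86) and clpB (-1.71) were lower and groL, the chaperonin gene, was higher (0.78). In the replication list the gyrase gene gyrA was higher (1.63) and dnaG (-1.12) and ftsZ with thiD (-1.25) were lower. The translation list had 5 higher and 3 lower of 25 (4 and 1 of 16 with exact symbols), and the NDH-1 list 1 each of 6. Carbon fixation had 1 of 3 lower, clock-related regions 1 of 2, and phycobilisome, glycogen and RNA polymerase lists had none past the rule. Over all 7 comparisons, 4 of 77 list medians lay outside the central 95% of 10000 random lists matched on mean index, where chance would place 3.85. They were photosystem II (-0.86) and NDH-1 (-0.84) for rel- against wild type at dusk, and the electron carriers for rel- against wild type at dawn (-0.67) and for wild type at dawn against 12 h (0.71).

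The difference between dark and dusk libraries was partly shared between the strains. Of the regions higher in darkness 30 were counted in both, including atpH, rplC to rplO, ndhN and polA, where independent lists would share 11.6. Of the lower regions 44 were counted in both, including mutS, rpsR, ccmN and dnaJ, against 11.4. Opposite calls were rare, with 3 regions higher in wild type and lower in rel- (14.6 for independent lists) and 1 the other way (9.08). Each strain was set against its own dusk library, so the lists share no library. Across regions, which are not independent replicates, the mean darkness changes had Pearson's r of 0.52 and Spearman's rho of 0.45. The darkness change itself was at least 1.5-fold higher in rel- at all 3 dark times for 74 regions and lower for 97. No noise simulation was run for these counts.

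**Figure D2:**
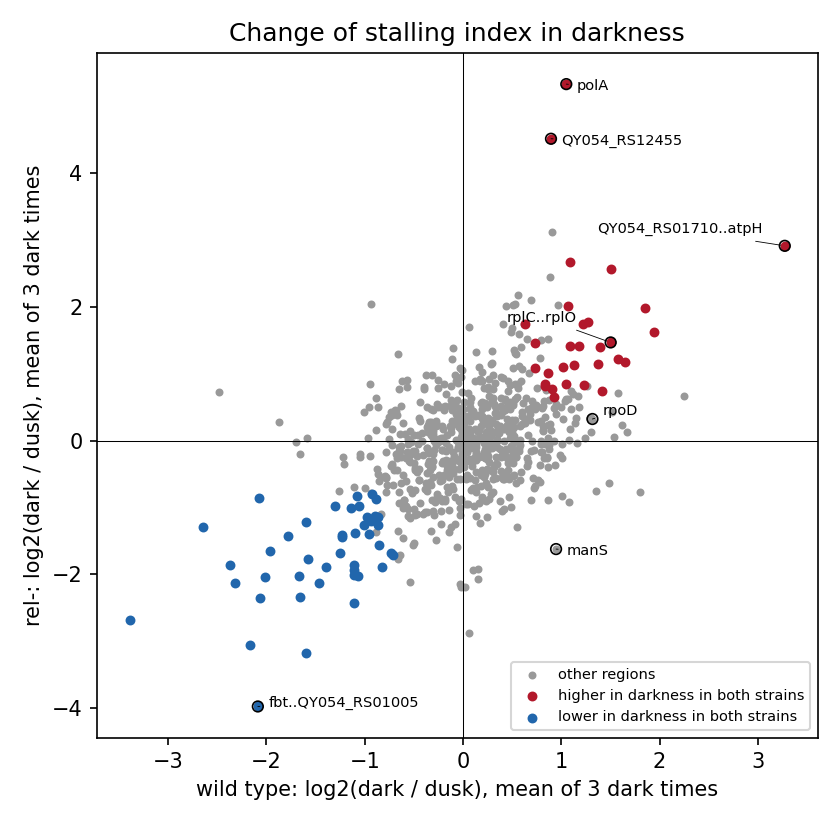
Mean log2 ratio of the dark to the dusk stalling index over the 3 dark times in wild type (horizontal) and rel- (vertical), 1 point per region. Red points are the 30 regions higher in both strains and blue points the 44 lower in both; polA lies at 5.33 in rel- and manS is higher in wild type only.

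**Figure D3:**
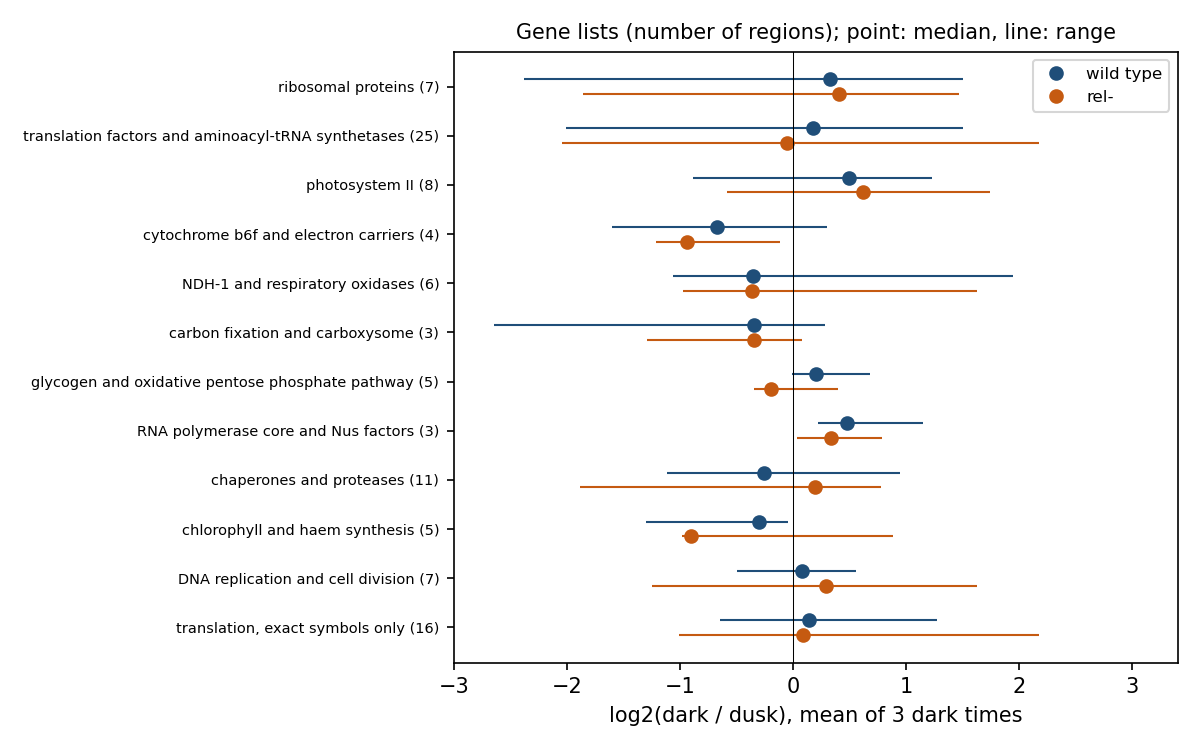
Median log2 ratio of the dark to the dusk index per gene list, as a point, with the range over its regions as a line, in wild type and rel-. The lines of most lists cross 0; the electron carrier medians lie at -0.67 in wild type and -0.94 in rel-.

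In darkness most regions had a lower index in rel- than in wild type. The principal sigma factor gene rpoD (positions 642767 to 643966) was 5.03-fold lower in rel-, with 3.76, 3.44 and 4.96 against 16.8, 22.7 and 21.5. The thiamine synthesis gene thiC was 7.70-fold lower (0.454 against 4.00 at 12 h), the membrane protease gene ftsH 4.75-fold lower and the riboflavin synthesis gene ribBA 4.30-fold lower. A smaller set was higher in rel-. It included QY054_RS12455 (15.9-fold), polA (6.14-fold), the recombinase gene recA (5.46-fold, 1.96 against 0.234 at 12 h), menD, a gene of quinone synthesis (4.04-fold), and the nusA region (3.08-fold).

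The rule counted 28 regions higher and 200 lower in rel-. The median log2 ratio of rel- to wild type was -0.29 at 4 h, -0.39 at 8 h and -0.36 at 12 h, while noise alone gave 0.04 higher and 0 lower regions on average. After each library was centred on its median, which removes the difference between library medians and so tends to balance the counts, 95 regions were higher and 95 lower, and rpoD (-1.92), thiC (-2.53), ftsH (-1.84) and ribBA (-1.69) were still lower. On that scale polA (3.03), recA (2.86) and menD (2.43) were still higher. Leaving out a dark time can only keep or raise the counts as deposited, as fewer times must then pass. It gave 44 higher and 255 lower without 4 h, 31 and 206 without 8 h, and 61 and 236 without 12 h. Dividing by the mock gave 47 higher as labelled and 27 with the mock labels exchanged. Others at the lower end were QY054_RS01380 with QY054_RS01375 (13.1-fold lower), QY054_RS05045 with QY054_RS05050 (8.19-fold), manS (4.08-fold), the sufU region (4.62-fold) and QY054_RS01305 (4.63-fold). Others at the upper end were QY054_RS05640 (4.96-fold) and QY054_RS09125 to QY054_RS09115 (5.99-fold).

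By list, many calls for rel- against wild type in darkness depended on the scale. The centred counts per list were added after the data were seen. As deposited, 4 of 8 photosystem II regions were lower in rel- and 1 psbA copy was higher, and after centring only the psbP region (-1.27) was lower, with the psbA copy still higher. Ribosomal protein regions were lower in 3 of 7 cases and higher in none, and after centring 1 was lower, that of nusG and rplK (-1.87), and 1 higher, that of rpsR (1.46). The translation list had 7 of 25 lower and none higher, and after centring 3 were lower, those of manS, thrS and clpS, and 7 higher, among them glyS, cysS and leuS. With exact symbols it had 5 of 16 lower, and after centring 1 lower and 4 higher, with glyS counted in 2 overlapping intervals. NDH-1 regions were lower in 3 of 6 cases (ndhN, ndhC and ndhD1), and after centring in 2 (ndhN -1.42, ndhC -1.18). Chaperone and protease regions were lower in 3 of 11 cases, and after centring in 2 (ftsH and clpS), with groL higher (0.96). Lower on both scales were the replication regions of ftsZ (-2.02, centred -1.61) and dnaG (-1.68, centred -1.26). The psaA to psaB region (-1.33, centred -0.91), the region annotated as cpcD/petH (-1.65, centred -1.24) and the atpH region (-1.25, centred -0.84) were also lower on both. Medians of the translation, electron carrier, carbon fixation, Nus factor and replication lists lay below 0 as deposited and above 0 after centring, so no direction is given for them.

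At dusk, before darkness, 233 regions already had a lower and 55 a higher index in rel-. The thiamine gene thiC was 3.96-fold lower (2.47 against 9.79), QY054_RS07620 was 4.26-fold lower and the region from QY054_RS04795 to QY054_RS04780, which holds the shikimate pathway gene aroQ, was 3.42-fold lower. Higher in rel- were wecB (2.99-fold), cbiD, a cobalamin synthesis gene (2.69-fold), QY054_RS10160 (2.90-fold) and QY054_RS07170 (2.86-fold). QY054_RS07170 (positions 1417540 to 1419879) stood out in the mocks, with 11.8 in the library labelled wild-type mock and 1.24 in that labelled rel- mock. It has no gene name in the annotation used, so whether it is the gene disrupted in rel- is not known, and its strain values are uncertain. Dividing by the mocks with exchanged labels, an alternative chosen after the data were seen, turned its dusk log2 ratio to -1.74. At dawn the imbalance ran the other way, with 123 regions higher and 65 lower in rel-. The median log2 ratio was -0.32 at dusk and 0.13 at dawn, and centring gave 122 higher and 101 lower at dusk and 69 higher and 105 lower at dawn. Noise alone gave 21.0 higher and 13.2 lower on average at dusk, and 21.0 and 13.4 at dawn.

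Between 12 h of darkness and dawn the index differed strongly at genes such as tsaD, ccmN and polA. In wild type tsaD, a tRNA modification gene, had 63.6 at 12 h and 3.49 at dawn, and the atpB region had 2.08 and 0.319. The region of ccmN had 0.309 at 12 h and 3.25 at dawn, and the region ending in cynS, the cyanase gene, had 1.19 and 6.88. In rel- polA had 79.9 at 12 h and 2.53 at dawn, and the region of nifJ and hypD, genes of pyruvate oxidation and hydrogenase maturation, had 11.9 and 1.74. The gene cofG had 3.25 and 36.9, and QY054_RS01240 had 1.46 and 23.9 in rel- and 1.73 and 10.6 in wild type.

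Between 12 h and dawn 108 regions were higher and 253 lower at dawn in wild type, against 264 higher and 109 lower in rel-. After centring the numbers were 189 and 165 in wild type and 166 and 197 in rel-, and noise alone gave 17.2 and 17.6 in wild type and 17.1 and 16.8 in rel-. In both strains 71 regions were higher and 69 lower at dawn, while 54 were lower in wild type and higher in rel- and 4 the reverse. To avoid sharing the 12 h library, regions were also taken by 4 h and 8 h against dusk alone. Of 111 such wild-type regions higher in darkness 92 were lower at dawn than at 12 h, where independent lists would share 36.9, and of 91 lower in darkness 50 were higher at dawn (12.9). In rel- the numbers were 57 of 106 (15.2) and 108 of 141 (48.9). The 8 h and 12 h libraries are nearly alike (r 0.98 in wild type and 0.97 in rel-), so the same dark value favours both calls. The overlaps thus exceed independent lists even without a reversal at dawn, and no test separates the 2.

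**Figure D4:**
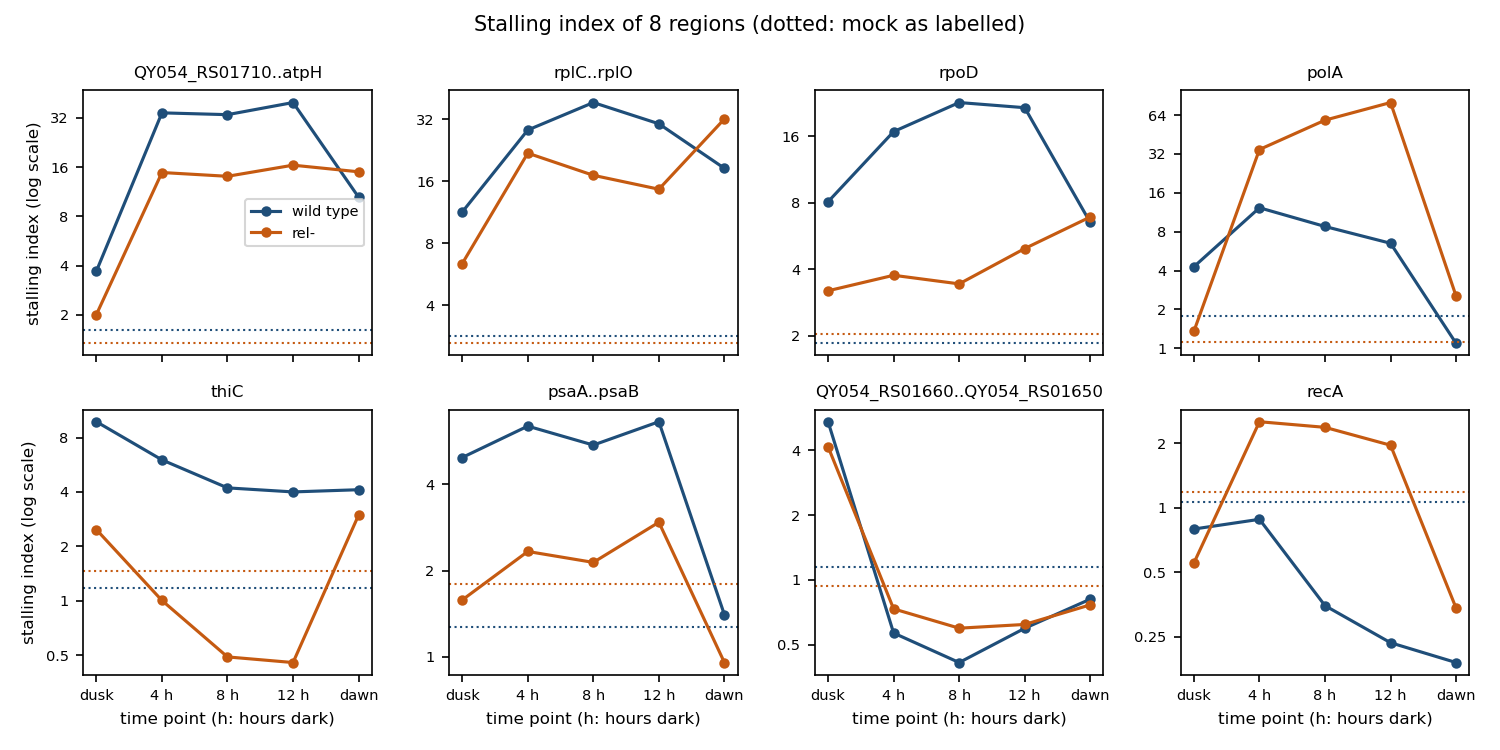
Stalling index (log axis) of 8 regions at dusk, after 4, 8 and 12 h of darkness and at dawn in wild type and rel-, 1 library per point, with the mock index of each strain, as labelled, as a dotted line. The rpoD index reaches 22.7 in wild type and 4.96 in rel- in darkness, and polA reaches 12.2 and 79.9.

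Taken over the time course, thiC, the photosystem I core genes and rpoD had a lower index in rel-, and menD and murA a higher one. In limma with time point as a block, thiC had a log2 difference of -2.26 ± 0.37 (SE, adjusted p = 0.0222, lower at 5 of 5 times) and psaA to psaB one of -1.24 ± 0.21 (adjusted p = 0.0222, 5 of 5). QY054_RS13115 (-1.30), QY054_RS07620 (-1.52) and QY054_RS00045 (-1.09) were likewise lower at all 5 times. Higher in rel- were menD (1.52 ± 0.27, limma adjusted p = 0.0229), murA, which encodes the first enzyme of peptidoglycan precursor synthesis (0.89 ± 0.18, adjusted p = 0.0245), and QY054_RS12455 (3.50 ± 0.61, adjusted p = 0.0222). For rpoD the difference was -1.65 (limma adjusted p = 0.0249, lower at 4 of 5 times).

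In limma 19 regions were higher and 108 lower in rel- after Benjamini-Hochberg adjustment, of 276 with an unadjusted p under 0.05. Centred libraries gave 49 higher and 69 lower, and dividing by the mock gave 61 and 192 as labelled and 21 and 116 with the mock labels exchanged. The adjusted count was sensitive to the pairs used: leaving out the 4 h, 8 h or 12 h pair left 0 regions in limma, with 180, 158 and 181 at an unadjusted p under 0.05, and leaving out dusk left 9 and 17. Each omission also lowers the 4 residual degrees of freedom. Leaving out dawn does so too, yet gave 44 and 271, and the 3 dark times alone, an alternative chosen after the data were seen, gave 85 and 307. Fewer degrees of freedom thus did not always lower the count. Where dawn was kept, lost power is not told apart from smaller differences. Time points are not replicates of 1 condition, so p here measures the strain difference against its own variation over time. In the lists, NDH-1 and chaperone regions were each lower in 3 cases, also when adjusted over the list alone. Photosystem II had 2 lower, or 4 adjusted over the list alone, the ribosomal list 1 lower, or 1 higher and 3 lower adjusted over the list alone, and the translation list 1 higher and 4 lower both ways (1 and 3 with exact symbols). The replication list had 2 lower and the Nus factor list 1 each way, both ways of adjusting alike. The sigma factor list had 1 lower, or 2 adjusted over the list alone, and ATP synthase 0, or 1 lower adjusted over the list alone. The phycobilisome list had 1 lower both ways, and the electron carrier, carbon fixation, glycogen, clock and chlorophyll lists had none by limma either way. On centred libraries, adjusted over all regions, limma gave 3 lower NDH-1 regions and 2 lower replication regions as before. It then gave 1 lower region each for photosystem II and chaperones, and 1 higher and 1 lower for the ribosomal and the translation list.

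The median log2 index differed between rel- and wild type by -0.31 at dusk, -0.36, -0.42 and -0.45 in darkness and 0.21 at dawn. The mean over the 5 times was -0.27 ± 0.27 (SD, n = 5), with a two-sided exact sign-flip permutation p of 0.125, where 5 pairs can give no p under 0.0625.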

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

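The tests of explanations in this part were chosen after the results were seen, except the count of other splits of the libraries, and 2 of them, on enrichment in rel- and on the dawn libraries, replaced first versions whose results had been seen.

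Several changes had opposite signs in the strains. The median log2 change in darkness against dusk was 0.081 in wild type and -0.038 in rel-. Both are small, and with 1 library each neither direction is established. The median change from 12 h to dawn was -0.25 in wild type and 0.27 in rel-. At 4 regions the 1.5-fold rule gave opposite calls in darkness: QY054_RS01305 (1.36 in wild type and -0.75 in rel-), manS (0.95 and -1.62), the sufU region (1.80 and -0.76) and 1 psbA copy (-0.885 and 0.64). None of these differences was tested, as each rests on 1 library per strain and time point, and near-identical psbA copies can share reads.

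For the lower rel- medians at dusk and in darkness, a larger share of background in rel- would pull indices toward the mock, and the SD of log2 index was smaller in rel- at 4 of 4 times. The 10th percentile was lower in rel- by a mean log2 difference of -0.10 (bootstrap interval -0.21 to -0.00176), which the first version took as excluding this. At dusk, though, the wild-type 10th percentile (0.869) lies above that of the mocks (0.848 and 0.838), and over the 3 dark times alone the difference was -0.11 (interval -0.25 to 0.021), so weaker enrichment stays open. For the reverse at dawn, an exchange of the dawn libraries stays open as well: 42 of 69 regions that set the strains apart at dusk and in darkness kept their direction after centring (60.9%, Wilson interval 49.1 to 71.5%), and in the first version r of the dawn strain difference with that at dusk, 4, 8 and 12 h was -0.036, 0.11, 0.20 and 0.25. The Wilson interval treats regions as independent, though all share the same dawn libraries and some intervals of the table overlap, so it is too narrow. Among regions picked after their values were seen, QY054_RS12455 (centred log2 ratio 4.40 in darkness, 4.95 at dawn) and QY054_RS07170 (1.82 at dusk, 1.38 in darkness, 3.31 at dawn) kept their direction. An exchange would turn the dawn ratio of every region, so both go against it, but they were picked from many. Across regions the strain ratio of the mocks had r of -0.27 with the polymerase ratio at dawn. At the other times r was -0.16 to -0.27, and an exchange would turn the sign at dawn. The wild-type dawn library was nearer to wild type than to rel- at 12 h (r 0.73 and 0.54). The rel- dawn library was also nearer to wild type (0.72 and 0.65), so the values go both ways. A strain difference that depends on light was not tested, as the labels leave unclear whether the light was on at dawn.

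For the difference between dark and dusk libraries, the change from dusk to 4 h and 8 h was set against that from dawn to 12 h. These changes use different libraries, and random deviations of the dusk library would leave them unrelated. Across regions r was 0.66 in wild type and 0.65 in rel-. The dark libraries are much alike, though, so both changes hold nearly the same dark values. A dusk library with compressed indices, or a deviation shared by the dark libraries, would also give a positive r. A change in enrichment alone would move regions above their mock value at dusk one way. The rarer direction made up 43.6% of their calls in wild type and 35.8% in rel-. These regions were picked by the dusk index, which is also the denominator of the change, so lower calls are favoured among them. The mock labels used are in doubt as well. The SD of log2 index was larger at 12 h of darkness than at dusk in wild type (1.29 and 1.06) and rel- (1.14 and 0.97), as a change in enrichment could give. The values argue only against random deviations at dusk. With regions chosen in this way and mock labels in doubt, the share of the rarer direction cannot decide on enrichment. A compressed dusk library, a deviation shared by the dark libraries and a change in enrichment, partial or sole, stay open. A response of polymerase to darkness or to the time of day, which the design does not separate, is a hypothesis beside them.

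In the mocks as labelled, the log2 ratio of rel- to wild type had r of -0.31 across regions with the mean polymerase ratio of the strains, and -0.29 without QY054_RS07170, so the relation does not rest on that region. Exchanged mock labels would give this sign, and exchanged strain labels on all polymerase libraries would give it at every time (weakest r -0.16), so these values do not tell them apart. Yet the library labelled rel- mock had about the same r with the polymerase libraries of both strains (0.33 to 0.45 with wild type, 0.36 to 0.43 with rel-), where an exchange would predict a preference for wild type. The cause stays open, and values divided by the mock are uncertain. The comparisons as deposited do not use the mocks, but exchanged polymerase labels would turn every direction given for rel- against wild type, including those of rpoD, thiC and menD.

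For the limma strain difference, 3 of 100 splits drawn from the 126 splits of the 10 libraries into 5 and 5, the real one included, called as many regions as the real 127. The highest other split called 283 regions. It sets the strains apart at the 3 dark times and puts both dusk libraries in 1 group and both dawn libraries in the other. With time point as a block, a pair kept in 1 group adds nothing to the estimated difference. The 283 calls thus rest on the real strain labels at the 3 dark times. Most of the splits drawn break the pairs of time points that the fit uses as blocks. Only 16 splits part every pair, too few for a share under 0.05. Of these, 13 were among the splits drawn, and 2 of them called as many, the real one and the one with the dawn labels exchanged, which called 179. The latter keeps the real labels at dusk and at the 3 dark times.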

How the results depend on the processing

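The fraction of regions past a rule is given in percent of the regions kept. The alternatives using exchanged mock labels, upstream genes and dark times alone were chosen only after the results were seen. Under alternatives 194 values that answer a comparison stayed within their limits, and 54 moved. The cause of each was not tested unless the setting itself shows it. A 2-fold threshold, which lowers counts by construction, gave 4.07% higher and 3.55% lower for wild type in darkness, 6.04% and 6.83% for rel- in darkness, and for rel- against wild type 1.58% and 12.4% in darkness, 1.97% and 10.5% at dusk and 5.26% and 2.63% at dawn. For dawn against 12 h it gave 6.57% and 18.4% in wild type and 20.2% and 7.49% in rel-. Centring on library medians, which removes the difference between library medians, gave 12.5% higher and 12.5% lower for rel- against wild type in darkness, 16.0% and 13.3% at dusk and 9.07% and 13.8% at dawn. For dawn against 12 h it gave 24.8% and 21.7% in wild type and 21.8% and 25.9% in rel-. In limma it gave 6.44% higher and 9.07% lower. Division by the mock gave 6.18% higher in rel- in darkness and, in limma, 8.02% higher and 25.2% lower. With the mock labels exchanged the values were 3.55%, 2.76% and 15.2%, close to those without division, so these moves depend on mock labels that are in doubt. Leaving out each dark time, which can only keep or raise a count, gave 4.07 to 8.02% higher for rel- against wild type in darkness. In limma, leaving out each time point gave 0 to 5.78% higher and 0 to 35.6% lower (counts of 0 for each dark time), dark times alone gave 11.2% and 40.3%, and the fit without the time block gave 1.58% higher. Without the regions that have a gene within 100 bp upstream on either strand, which kept 484 regions, medians were higher, at 2.17, 2.25, 2.16, 2.19 and 1.80 in wild type, 1.68, 1.72, 1.64 and 1.61 in rel- up to 12 h, and 1.198 in the library labelled wild-type mock. The mean median difference kept its sign in every setting tried. Among values of named regions and lists, 553 stayed the same, 191 moved and 33 no longer passed their test. Called values of named regions reversed in 1 case, the dusk ratio of QY054_RS07170 (-1.74) after division by the mocks with exchanged labels. List medians changed sign in 15 cases, 5 of them on the centred scale for rel- against wild type in darkness. The planned filter on same-strand upstream genes was not run, as the annotation used gives no strand, and the 600 bp filter removes no region. Depth is unknown, so no limit from it can be set.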

Other observations

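All values here were looked at after the results were seen. The strain ratio in darkness fell over groups of rising wild-type index, a grouping that itself favours such a fall. With regions divided into 5 groups of like size by their wild-type index at 4 h, the median log2 ratio of rel- to wild type at 12 h was 0.10 in the lowest group (153 regions), then -0.21, -0.43 and -0.66, and -1.05 in the highest (152 regions). At dawn the same groups had medians of 0.03, 0.12, 0.14, 0.21 and 0.25. The wild-type 12 h library, the denominator of the ratio at 12 h, is much like the 4 h library used for grouping (r 0.91). A falling gradient in darkness is thus favoured by the grouping alone, and regression toward the mean adds to it. Grouping by the rel- index was not tried. A larger share of background in rel-, left open above, would also give the gradient seen in darkness. At dawn the SD of log2 index was larger in rel- (1.12) than in wild type (1.03). No test separates these here.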
